A study of Mus musculus with 10 samples.

How the data were processed

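The series holds 10 Affymetrix Mouse 430 2.0 arrays, 1 for each of 5 male mice of 5 months and 5 male mice of 30 months, per the labels. The mice were B6C3F1 hybrids kept singly on a control diet, per the labels' protocols. RNA was extracted from frozen neocortex, messenger RNA was purified, and biotin-labelled cRNA was hybridized, per the labels' protocols.

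The deposited values were probe set intensities on a linear scale, for 45037 probe sets on each of the 10 arrays. The software GCOS is named in the submitters' processing notes, without a version or role. The background correction, the summary of probes into probe sets and the scaling between arrays are not given in the sources used here. The deposited intensities lay between 0.48 and 105818, and array medians were close to each other. A second deposited table of the series held the same intensities, equal in every cell within 0.005, beside a comparison of the 30-month with the 5-month arrays. That table gave a signed fold change, its lower bound and a p-value for each probe set, per the file headers. The authors' criteria were a lower bound of the fold above 1.2 in either direction and a p-value of at most 0.1, per the file headers. The p-value cell of 62 probe sets held no number, and the program that made the comparison is not given in the sources used here. Control probe sets of the array were omitted from that table, per the file headers.

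Probe sets were named through their gene identifiers or accessions from the array annotation, updated with a gene table of the GRCm38.p6 assembly. Of the 45037 probe sets, 36299 had 1 gene (36239 by gene identifier and 60 by accession), 1261 had several genes and 7477 had none. These covered 17876 genes. Probe sets with several genes or none were left out of gene counts, so that C4b was not tested.

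Signals under 1, of which there were 55, were set to 1, and log2 was taken with the deposited scaling kept. Detection calls were not used here, so the fallback rule applied: a probe set was tested if its mean log2 signal over all arrays exceeded the median of all probe sets, 6.89. For each gene the tested probe set with the highest mean was kept, which gave 11963 genes from 22518 tested probe sets. Each gene was fitted with limma (version 3.58.1, R 4.3.3) with a term for age and a variance trend, two-sided. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 6431 genes. Gene lists of cell types and pathways, 33 with 495 entries, were fixed before the data were examined, as were the design, the named-gene rule and the alternatives unless stated otherwise. All 495 entries were found in the gene table, and 73 were not tested. The 32 lists with at least 3 tested genes were tested with fry from limma, adjusted over the lists, with camera beside it at a preset correlation of 0.01 and at an estimated one. Array measures were compared by an exact permutation test of the difference of means, two-sided, whose smallest p is 0.00794.

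Genes were named by a rule. It took the 12 higher and 12 lower genes with the largest change among called genes whose old arrays all lay on one side of the young arrays, without clone or predicted-gene symbols and without probe sets ending in x_at. It added up to 4 called members of each list with the smallest adjusted p, and Gfap, C4b, Apod and Sirt1 whatever their values. Genes outside the rule are said to be so in the report, and the closing section also names single genes and marker genes outside it.

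The gene fit was tested on simulated data for the comparison of 30 with 5 months over 11963 genes. It recovered 35 of 67 genes changed by a log2 change of 0.32 (52.2%), 61 of 67 changed by a fold of 1.5 and 66 of 66 changed by a fold of 2, and 10 unchanged genes were called, 5.81% of the calls. For the gene lists, fry called none of the 32 lists in 94 of 100 simulated draws over 11963 genes without a change, and at most 2 in a draw. With 3 lists shifted, all 3 were called in 99 of 100 draws. The simulated genes varied independently of each other, and far fewer of them were changed than were called in the data. In the data the correlation estimated within a list reached 0.63 for the immediate-early and 0.68 for the myelin list. The simulated rates therefore need not hold for such lists.

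The alternatives covered quantile normalization, setting each array to the same median, adding 16 or 64 to the signal, other filters, other ways to combine probe sets, other variance models and array weights. They also covered other thresholds, separation by rank, mouse number as a replicate block, and leaving out each array in turn. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The replicate numbers name mice and did not pair the arrays of the 2 ages. The number of arrays limits the precision of every value, and each value rests on 1 array per mouse.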

Results

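Gene expression was measured in the neocortex of 10 male mice of the B6C3F1 strain, the hybrid offspring of C57BL/6 and C3H parents. There were 5 mice aged 5 months and 5 mice aged 30 months, and the RNA of each mouse was hybridized to its own Affymetrix Mouse 430 2.0 array. The deposited table gave the signal of 45037 probe sets on each array, and the median signal of an array lay between 114.5 and 122.6. The comparison implied by the labels is which transcripts of the neocortex differ between young adult and old mice. With 5 arrays at each age, the number of arrays limits the precision, and the median standard error of a log2 change was 0.07.

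Transcripts of reactive astrocytes, of microglia and complement, of antigen presentation, of lysosomes and of cholesterol synthesis were higher in the old neocortex, and immediate-early transcripts of neuronal activity were lower. These list calls rest on fry, and in camera with an estimated correlation 0 of 32 lists passed (lowest adjusted p = 0.571). The largest increase among the genes named by the rule was that of Gfap, the intermediate filament protein of astrocytes, at 4.13-fold (log2 change 2.04, SE 0.08, adjusted p = 3.93e-09). Its log2 signal was 9.11 ± 0.14 at 5 months and 11.15 ± 0.12 at 30 months (SD, n = 5 at each age). Of 11963 genes tested, 4068 were higher and 1466 were lower at 30 months, which is 46.3% of the genes. Of the genes called, 73.5% were higher, but after quantile normalization 2745 were higher and 2433 lower (53% higher), and with each array set to the same median 2602 were higher and 2702 lower (49.1% higher). The balance of higher against lower genes moved with the scaling of the arrays. Between the deposited scaling and quantile normalization, 2727 genes were called higher in both, 1456 were called lower in both, and 0 changed direction. Most changes were small: the median log2 change was 0.32 for the higher and −0.33 for the lower genes, and 435 higher and 237 lower genes reached a fold of 1.5. In 2927 genes each of the 5 old arrays lay above each of the 5 young arrays, and in 688 genes each lay below. Together these were 30.2% of the genes tested, against 0.794% given by chance.

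Among the 12 genes with the largest increases were several of immune cells and of sterol metabolism. Cd74, the invariant chain of MHC class II, rose 2.82-fold, Ifitm3, an interferon-induced membrane protein, rose 2.83-fold, and Tyrobp, a signalling adaptor of microglia, rose 2.42-fold. C1qa, a chain of the complement component C1q, rose 2.50-fold, and Insig1, a regulator of sterol synthesis in the endoplasmic reticulum, rose 2.54-fold. Tm7sf2, a sterol reductase, rose 2.63-fold, and Pam, the enzyme that amidates neuropeptides, rose 2.67-fold. The others were Rpl27a, a ribosomal protein gene, at 3.05-fold, Yjefn3 at 2.82-fold, Wdr25 at 2.59-fold and Upf1, a helicase of nonsense-mediated decay, at 2.47-fold. Among the 12 largest decreases, Ung, a uracil-DNA glycosylase, had a log2 change of −1.38 (SE 0.35) and Tcf7l1, a transcription factor of the Wnt pathway, one of −1.37 (SE 0.24). Prr27 had a log2 change of −1.34, Plekha6 of −1.19, Nmur1, a receptor of neuromedin U, of −1.17, Clec1a of −1.17 and Etv3, an ETS transcription factor, of −1.12. Serpina1c, Plcxd1, Tmtc2, Ttf1 and Angptl4 had log2 changes from −1.10 to −1.05. These 12 decreases shared a pattern between arrays: except in Ttf1, 30-month mouse 2 had the highest signal of the old mice. Tcf7l1, for example, was 1678 in mouse 2 and 496 in mouse 6, and Prr27 was 2003 and 846. They are thus not separate observations, and the cause was not tested. Ung was weak, with a mean log2 signal of 6.72 at 30 months, below the filter value of 6.89. Yjefn3 was weak too, with a mean of 6.62 at 5 months, and Wdr25 ranged from 79.9 to 193 in linear signal in the young mice. Apod, a lipid-binding protein of glia, rose 2.25-fold (adjusted p = 1.87e-06), and the deacetylase gene Sirt1 had a log2 change of −0.11 that did not pass the test (adjusted p = 0.329). In 412 of the 2514 called genes with several tested probe sets, another probe set of the gene was called in the opposite direction.

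**Figure D1:**
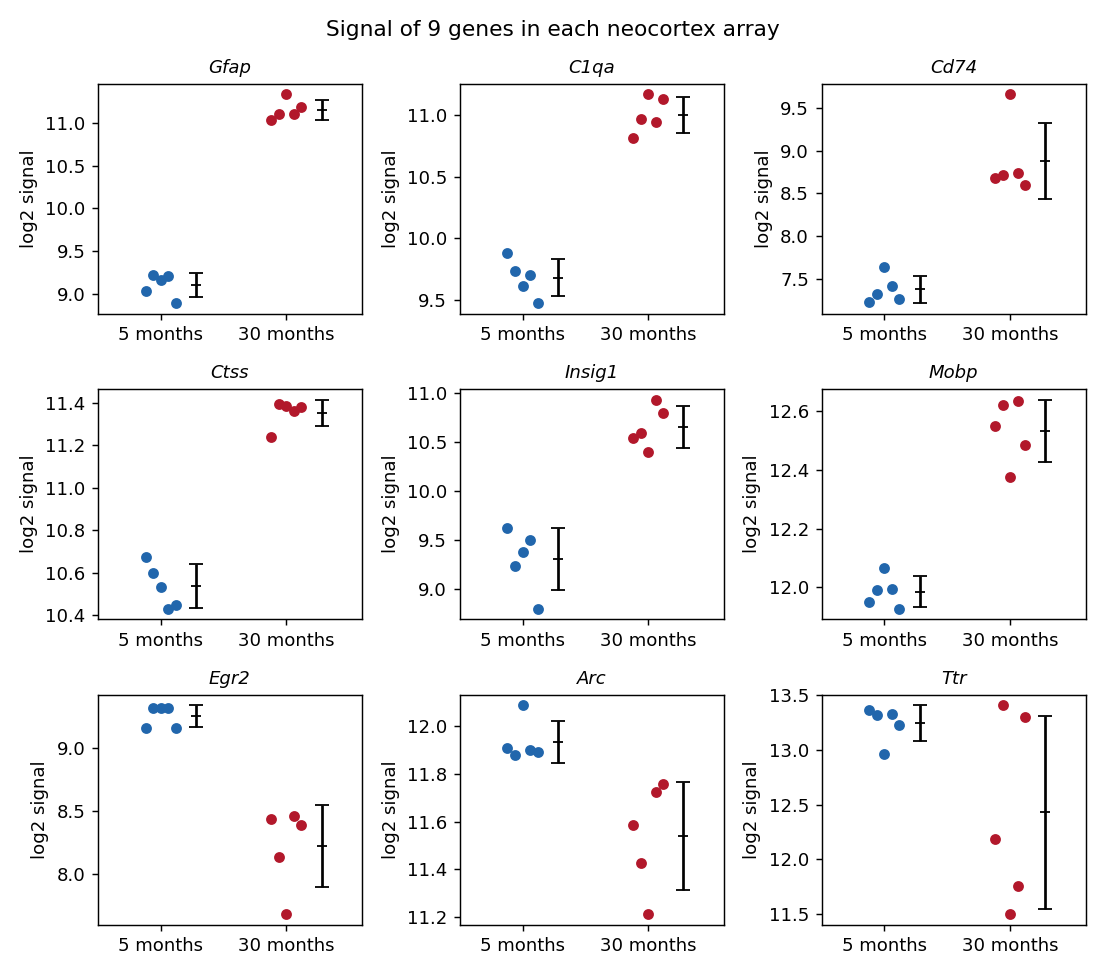
Log2 signal of 9 genes on each array, with 5 months in blue and 30 months in red; each point is 1 mouse and the bars are the mean ± SD. In Gfap, C1qa, Cd74, Ctss, Insig1 and Mobp the 5 old arrays lay above the 5 young arrays, in Egr2 and Arc they lay below, and in Ttr the old arrays ranged from 2898 to 10851 in linear signal.

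Of 33 gene lists fixed before the data were examined, 32 had at least 3 tested genes, and fry called 14 higher and 1 lower at 30 months. The fry test asks whether the genes of a list move, on balance, one way, and its mixed form whether they change in either direction; neither compares a list with other genes. In the mixed form 29 of the 32 lists passed, among them lists whose members went both ways, such as the glutamatergic (adjusted p = 1.10e-07) and receptor (adjusted p = 3.47e-07) lists. The 3 that did not pass it were the interferon (0.0617), sirtuin (0.119) and choroid plexus (0.457) lists. With camera, which does compare a list with the other genes, 6 lists passed at a preset correlation (complement, astrocyte markers, reactive astrocyte, immediate-early, cholesterol synthesis and lysosome). With a correlation estimated from the arrays, 0 of the 32 lists passed in camera, where the lowest adjusted p was 0.571. For several lists whose median change was above 0, the sign of the camera test lay below the other genes. These were the interferon, pan-neuronal, glutamatergic, interneuron, meninges, striatum, receptor, heat shock, p53, sirtuin, proteasome and immature neuron lists. None of them passed in camera, where their lowest adjusted p was 0.447 at the preset and 0.736 at the estimated correlation, both for the meninges. The counts of higher and lower members were the same in 25 lists when adjusted over the list alone, and the 7 lists in which they differed are given with theirs. All changes below are log2 changes, 30 months minus 5 months, and list medians are over the tested members. The median over all 11963 tested genes was 0.08, and 4068 of them were called higher. The medians of the interneuron, calcium, antioxidant and clock lists, 0.07 to 0.10, lay near that value. Their fry calls therefore do not set them apart from the general shift.

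Astrocyte genes rose as a group. Of 13 tested astrocyte markers, 10 rose, 0 fell and 3 did not pass the test (median 0.32, adjusted p = 4.36e-04, and adjusted p = 0.614 with an estimated correlation). Aldh1l1, a folate enzyme used as a general astrocyte marker, rose by 0.59, and the glutamate transporter Slc1a3 rose by 0.52. The water channel Aqp4 rose by 0.73, although 1 of its 3 tested probe sets was called in the opposite direction. Of 9 genes of reactive astrocytes, 6 rose, 0 fell and 3 did not pass (median 0.80, adjusted p = 4.36e-04, and adjusted p = 0.614 with an estimated correlation). Besides Gfap these included the intermediate filament gene Vim, which rose by 1.24, the sphingosine phosphate receptor S1pr3, which rose by 1.14, and the protease inhibitor Serpina3n, which rose by 1.03. The median was the value of Cp, which read 477 in 30-month mouse 4 and 104 to 173 in the other old mice. Its call (adjusted p = 0.0459) was lost with each array set to the same median (0.0797). It was also lost without any single 5-month mouse (0.0682 to 0.0794). With each array set to the same median, 6 of the 13 astrocyte markers and 5 of the 9 reactive genes were higher and 0 lower. Adjusted over the list alone, the counts were also 10 and 6 higher with 0 lower.

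The complement, microglia, phagocytic and antigen presentation lists were called higher in the old mice, and the interferon list was not called. Of 6 complement genes, 5 rose, 0 fell and 1 did not pass (median 0.58, adjusted p = 8.57e-06, and adjusted p = 0.571 with an estimated correlation). C1qb rose by 1.19 and C1qc by 0.68, and these genes encode chains of the initiating component C1q. Of 13 microglia markers, 8 rose, 3 fell and 2 did not pass (median 0.41, adjusted p = 7.88e-06, and adjusted p = 0.571 with an estimated correlation). Ly86, a partner of a Toll-like receptor homologue, rose by 1.19 and the Fc receptor gene Fcgr3 by 0.95. The 3 markers that fell, named after their values were seen, were Laptm5 (−0.50), the fractalkine receptor gene Cx3cr1 (−0.40) and the growth factor receptor gene Csf1r (−0.26). Each of these 3 was also called lower under both other scalings. Of 11 genes of phagocytic microglia, 5 rose, 0 fell and 6 did not pass (median 0.31, adjusted p = 7.39e-05, and adjusted p = 0.614 with an estimated correlation). Spp1, encoding osteopontin, rose by 1.15, Cd68, a lysosomal protein of macrophages, by 0.86, and lipoprotein lipase, Lpl, by 0.54. With each array set to the same median, 1 phagocytic gene was lower.

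Of 11 genes of antigen presentation, 7 rose, 0 fell and 4 did not pass (median 0.42, adjusted p = 0.00123, and adjusted p = 0.697 with an estimated correlation). The MHC class I gene H2-D1 rose by 1.24, the peptide transporter gene Tap2 by 0.84 and the immunoproteasome gene Psmb10 by 0.42. In Cd74, H2-D1 and Ifitm3 the signal of 30-month mouse 4 stood above that of the other old mice. Of 11 interferon-response genes, 2 rose, 1 fell and 8 did not pass (median 0.08, adjusted p = 0.678). Ifitm3 also rose without mouse 4, by 1.12, and Ifi27, an interferon-induced protein of the mitochondrion, had a change of −0.63. Ifi27 shared the array pattern of the largest decreases, so it is not a separate observation. Of the old mice it was highest in 30-month mouse 2, at 2359, against 1279 in mouse 6. Under either other scaling 1 interferon gene was higher and 2 were lower. The median of this list was −0.01 with each array set to the same median and −0.06 without mouse 4. Adjusted over the list alone, the counts of these 5 immune lists did not change.

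Lysosomal and sterol genes rose broadly. Of 18 lysosome genes, 15 rose, 0 fell and 3 did not pass (median 0.49, adjusted p = 2.47e-05, and adjusted p = 0.571 with an estimated correlation). The cysteine protease gene Ctss rose by 0.81, progranulin, Grn, by 0.74, and the membrane protein genes Lamp2 and Scarb2 by 0.55 and 0.47. After quantile normalization 14 of the 18 were higher and 1 lower, and with each array set to the same median 13 were higher and 2 lower. Of 16 genes of cholesterol synthesis, 12 rose, 0 fell and 4 did not pass (median 0.33, adjusted p = 1.39e-04, and adjusted p = 0.571 with an estimated correlation). Besides Insig1, the sterol reductase gene Dhcr7 rose by 0.86 and the demethylase gene Cyp51 by 0.56. Under either other scaling 9 of the 16 were higher and 0 lower. Adjusted over the list alone, the counts were 15 and 12 higher with 0 lower.

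Myelin and vascular genes were higher as well. Of 16 genes of mature oligodendrocytes and myelin, 9 rose, 0 fell and 7 did not pass (median 0.26, adjusted p = 0.0194, and adjusted p = 0.931 with an estimated correlation). The iron carrier transferrin, Trf, rose by 0.96, the cytoskeletal gene Ermn by 0.68 and the myelin gene Mobp by 0.55. The call of this list was lost over the 8 mice numbered 2 to 5 at both ages (adjusted p = 0.0761). Of 11 genes of oligodendrocyte precursors, 4 rose, 2 fell and 5 did not pass (median 0.14, adjusted p = 0.0889). Lhfpl3 rose by 0.42 and the transcription factor gene Olig1 by 0.35, and Gpr17, a receptor of differentiating precursors, had a change of −0.53. The precursor list was called higher without 5-month mouse 1 (adjusted p = 0.0435) or mouse 2 (adjusted p = 0.0471). Of 8 genes of endothelial cells and pericytes, 5 rose, 0 fell and 3 did not pass (median 0.44, adjusted p = 1.39e-04, and adjusted p = 0.571 with an estimated correlation). The glucose transporter gene Slc2a1 rose by 0.84, the VEGF receptor gene Flt1 by 0.66 and the pericyte receptor gene Pdgfrb by 0.42. Under either other scaling 3 of these 8 were higher and 0 lower, and 7 of the 16 myelin genes were higher and 0 lower. For the precursors the counts were 3 higher and 2 lower after quantile normalization, and 3 and 3 with each array set to the same median. Adjusted over the list alone, the counts of these 3 lists did not change.

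**Figure D2:**
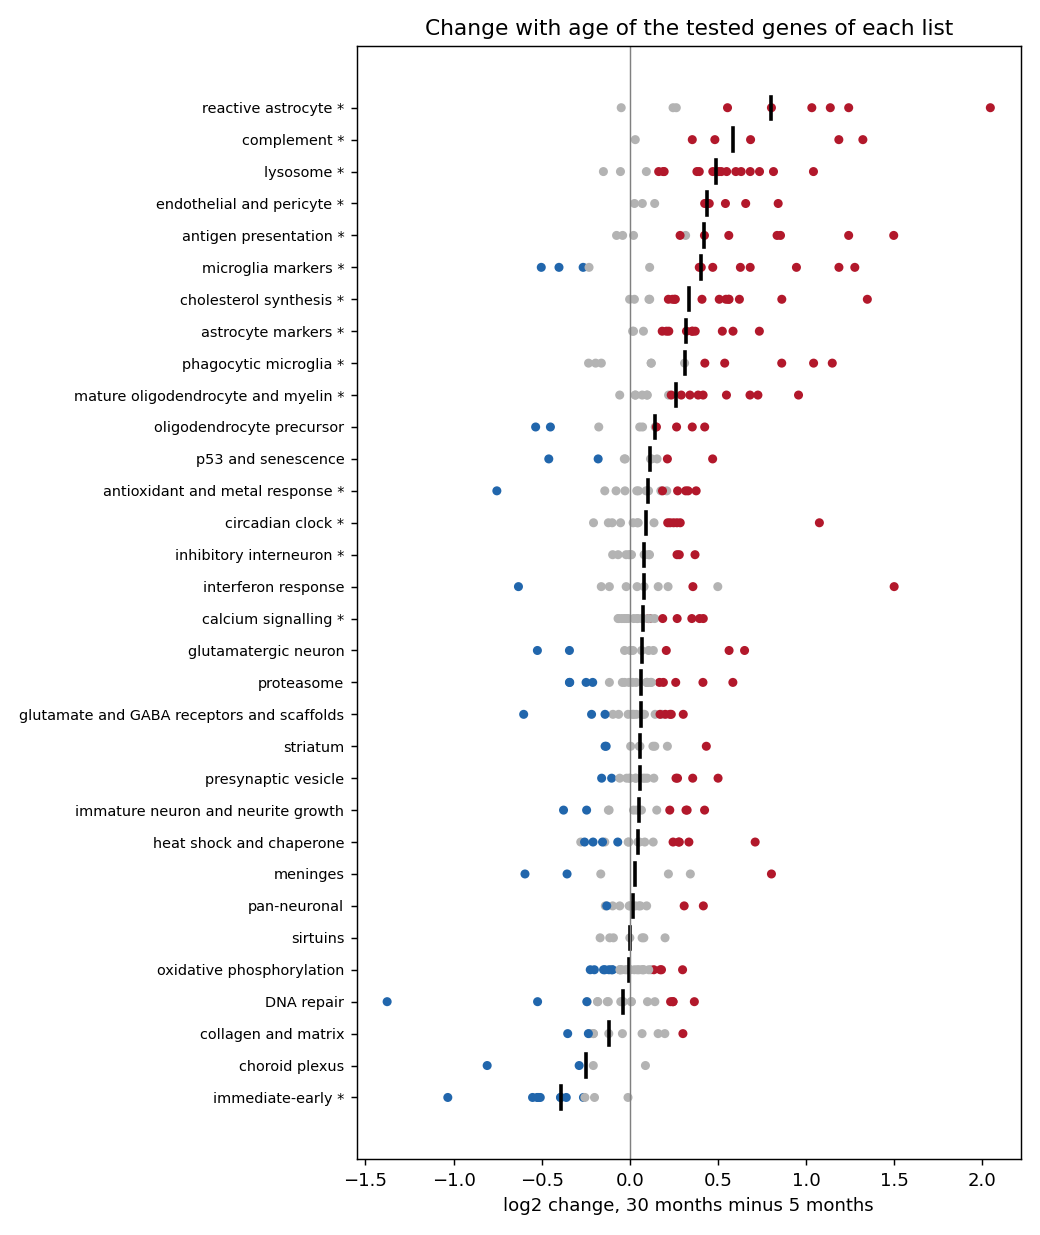
Log2 change of each tested gene of each list, 30 months minus 5 months, with 1 point per gene: red for genes called higher, blue for genes called lower and grey for genes not called; black bars are list medians and a star marks a list with an adjusted p under 0.05 in fry. The medians ran from 0.80 in the reactive astrocyte list to −0.39 in the immediate-early list, with the deposited scaling; several of the medians near 0 changed sign under another scaling.

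Immediate-early genes, which neurons induce on activity, fell. Of 12 tested, 0 rose, 9 fell and 3 did not pass (median −0.39, adjusted p = 0.0260, and adjusted p = 0.571 with an estimated correlation). The transcription factor gene Egr2 had a change of −1.03, the synaptic gene Arc of −0.39, the nuclear receptor gene Nr4a1 of −0.36 and Egr1 of −0.26. The counts were the same under both other scalings and when adjusted over the list alone. The call of the list was lost without 5-month mouse 1 (adjusted p = 0.0696), mouse 2 (adjusted p = 0.0521) or mouse 3 (adjusted p = 0.0606), and over the 8 mice numbered 2 to 5 at both ages (adjusted p = 0.0833).

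The general neuronal and synaptic lists were not called in one direction, and their members went both ways. Of 13 pan-neuronal genes, 2 rose, 1 fell and 10 did not pass (median 0.02, adjusted p = 0.354), and adjusted over the list alone 2 rose and 0 fell. The heavy neurofilament gene Nefh rose by 0.42 and the tubulin gene Tubb3 by 0.31. Of 11 genes of glutamatergic neurons, 3 rose, 2 fell and 6 did not pass (median 0.07, adjusted p = 0.198). The upper-layer gene Cux2 rose by 0.65, the vesicular glutamate transporter Slc17a7 rose by 0.56, and Rorb, a gene of layer 4, had a change of −0.52. Of 19 genes of glutamate and GABA receptors and scaffolds, 5 rose, 3 fell and 11 did not pass (median 0.06, adjusted p = 0.113), and the NMDA receptor gene Grin1 rose by 0.23. The AMPA receptor gene Gria2 had a change of −0.22, a call that was lost when the probe sets of a gene were averaged (−0.07, adjusted p = 0.186). The receptor list was called higher without 5-month mouse 2 (adjusted p = 0.0317). Of 16 presynaptic genes, 4 rose, 2 fell and 10 did not pass (median 0.06, adjusted p = 0.0889), and adjusted over the list alone 4 rose and 1 fell. The priming factor gene Unc13a rose by 0.50, Rims1 of the active zone by 0.36 and the vesicle gene Sv2b by 0.27. After quantile normalization 2 pan-neuronal genes were higher and 3 lower, and with each array set to the same median 2 were higher and 5 lower. In the same order of scalings the glutamatergic counts were 2 higher and 2 lower, then 2 and 3, and the receptor counts 2 higher and 3 lower, then 2 and 4. The presynaptic counts were 5 higher and 2 lower, then 4 and 4. With each array set to the same median, the medians of these 4 lists were −0.08, −0.03, −0.03 and −0.04.

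Of 13 genes of inhibitory interneurons, 3 rose, 0 fell and 10 did not pass (median 0.08, adjusted p = 0.00711, and adjusted p = 0.951 with an estimated correlation). The calcium-binding protein gene Pvalb rose by 0.37. This list's call was lost after quantile normalization (median −0.01, adjusted p = 0.410). Camera at the preset correlation gave the list a sign below the other genes, but it did not pass (adjusted p = 0.921). The counts were 2 higher and 1 lower after quantile normalization, and 3 and 3 with each array set to the same median. Of 20 genes of calcium signalling, 6 rose, 0 fell and 14 did not pass (median 0.07, adjusted p = 0.0488, and adjusted p = 0.951 with an estimated correlation). The calcium channel gene Cacna1a rose by 0.35. The call was lost after quantile normalization (adjusted p = 0.120), without the filter (0.0604), with the probe sets of a gene averaged (0.126) and over the 8 mice numbered 2 to 5 (0.145). It was also lost without 5-month mouse 1 (0.0863), 4 (0.0750) or 5 (0.0633) or 30-month mouse 2 (0.107), 5 (0.113) or 6 (0.101), or without 30-month mice 4 and 6 together (0.0879). With each array set to the same median 4 members were higher and 5 lower. Of 12 genes of immature neurons and neurite growth, 4 rose, 2 fell and 6 did not pass (median 0.05, adjusted p = 0.283). The tubulin gene Tubb2b rose by 0.42, doublecortin, Dcx, rose by 0.32, and the transcription factor gene Sox11 had a change of −0.38. Its median was −0.04 with each array set to the same median, with 3 members higher and 3 lower.

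Among lists of metabolism and stress, the antioxidant and clock lists were called higher, with medians near the 0.08 of all tested genes. Of 16 antioxidant and metal-response genes, 5 rose, 1 fell and 10 did not pass (median 0.10, adjusted p = 0.0180, and adjusted p = 0.951 with an estimated correlation). Catalase, Cat, rose by 0.38 and the glutathione transferase gene Gstm1 by 0.27, and Gclm, a subunit of the enzyme that starts glutathione synthesis, had a change of −0.75. Gclm shared the array pattern of the largest decreases, so it is not a separate observation. Of the old mice it was highest in 30-month mouse 2, at 1501, against 729 in mouse 6. After quantile normalization 5 antioxidant genes were higher and 3 lower, and with each array set to the same median 3 were higher and 3 lower (median 0.01). Of 14 circadian clock genes, 6 rose, 0 fell and 8 did not pass (median 0.09, adjusted p = 7.77e-04, and adjusted p = 0.931 with an estimated correlation). The transcription factor gene Npas2 rose by 1.08 and the repressor gene Cry2 by 0.29. Under either other scaling 2 of the 14 were higher and 0 lower, and the median with each array set to the same median was −5.70e-04. The call of the clock list was lost with the probe sets of a gene averaged (median 0.01, adjusted p = 0.145). Of 30 genes of oxidative phosphorylation, 4 rose, 7 fell and 19 did not pass (median −0.00253, adjusted p = 0.760), and adjusted over the list alone 4 rose and 6 fell. Uqcrfs1 of complex III had a change of −0.20, Atp5b of the ATP synthase of −0.14, and Ndufa9 of complex I rose by 0.30. With each array set to the same median, 1 of the 30 was higher and 13 were lower.

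Of 17 heat shock and chaperone genes, 5 rose, 4 fell and 8 did not pass (median 0.05, adjusted p = 0.156), and the chaperone genes Hspa2 and Cryab rose by 0.71 and 0.34. Of 20 proteasome genes, 5 rose, 4 fell and 11 did not pass (median 0.07, adjusted p = 0.494), and adjusted over the list alone 6 rose and 4 fell. After quantile normalization 4 proteasome genes were higher and 5 lower, and with each array set to the same median 2 were higher and 6 lower. The ATPase subunit gene Psmc1 rose by 0.58 and the core subunit gene Psma4 had a change of −0.34. Of 19 DNA repair genes, 4 rose, 3 fell and 12 did not pass (median −0.04, adjusted p = 0.473), and adjusted over the list alone 3 rose and 3 fell. Besides Ung, Brca1 had a change of −0.52, and Brca2 rose by 0.37. Brca1 was weak, with a mean log2 signal of 6.88 at 30 months, just below the filter value of 6.89. After quantile normalization the DNA repair list was called lower (median −0.14, adjusted p = 0.00599), with 1 gene higher and 6 lower, and with each array set to the same median 1 was higher and 7 were lower. Of 9 genes of the p53 response and senescence, 2 rose, 2 fell and 5 did not pass (median 0.12, adjusted p = 0.238), and the stress gene Gadd45g had a change of −0.46. Of 7 sirtuin genes, 0 rose, 0 fell and 7 did not pass (median 1.76e-04, mean −0.00373, fry direction lower, adjusted p = 0.915), while after quantile normalization the list was called lower (median −0.09, adjusted p = 0.00371). With each array set to the same median, 4 heat shock genes were higher and 5 lower, 1 p53 gene was higher and 2 were lower, and 0 sirtuin genes were higher and 2 lower. The medians of the heat shock, proteasome and p53 lists were −0.03, −0.03 and −0.00200 after quantile normalization.

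Lists of neighbouring tissue were not called in one direction over the 10 arrays. Of 4 choroid plexus genes, 0 rose, 2 fell and 2 did not pass (median −0.25, adjusted p = 0.286). Without 30-month mouse 3 the choroid plexus list was called lower (median −0.44, adjusted p = 0.0377). The choroid plexus gene Ttr, a thyroid hormone carrier, had a change of −0.81 (adjusted p = 0.0445), which did not pass after quantile normalization (adjusted p = 0.103) or without any single 5-month mouse or 30-month mouse 2, 4 or 5. With 1 of these mice left out the change of Ttr lay between −0.88 and −0.58, with an adjusted p between 0.0544 and 0.113. Of 6 genes of the meninges, 1 rose, 2 fell and 3 did not pass (median 0.03 and mean 0.04, but fry direction lower, adjusted p = 0.424), and the matrix gene Islr had a change of −0.36. Of 9 genes of the striatum, 1 rose, 2 fell and 6 did not pass (median 0.06, adjusted p = 0.344), adjusted over the list alone 1 rose and 0 fell, and the gene that rose was the G protein regulator Rgs9 (0.43). Of 11 genes of collagen and matrix, 1 rose, 2 fell and 8 did not pass (median −0.12, adjusted p = 0.584), and adjusted over the list alone 1 rose and 0 fell. The basement membrane gene Col4a1 rose by 0.30, a call that was lost when the probe sets of a gene were averaged (0.14, adjusted p = 0.116). Under either other scaling 1 matrix gene was higher and 4 were lower. The medians of the meninges and striatum lists were −0.07 and −0.04 with each array set to the same median. Of the 8 blood-cell genes only the haemoglobin gene Hba-a1 was tested; it lies outside the rule for named genes and had a change of −0.10 (adjusted p = 0.602).

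The array medians did not differ detectably between the ages. The median log2 signal was 6.91 ± 0.03 at 5 months and 6.89 ± 0.04 at 30 months (SD, n = 5 at each age, difference −0.02, exact permutation p = 0.357, two-sided). Measures chosen after the data were seen did differ: the upper quartile was 0.09 higher at 30 months, the lower quartile had a difference of −0.08, and the median over the tested genes was 0.10 higher. Each of these had an exact permutation p of 0.00794, the smallest this design can give, and 0.0106 adjusted over the 4 measures. Over the tested genes, arrays correlated at 0.985 to 0.994 within 5 months, at 0.982 to 0.991 within 30 months and at 0.955 to 0.981 between the ages, across genes, which are not independent replicates. The labels give no batch to test. All 5 columns of the old mice carry a mark in their names that no column of the young mice has, so that a difference in handling behind this mark and age cannot be told apart. In the authors' deposited table of the same comparison, 4034 probe sets were marked as changed, 2667 higher and 1367 lower at 30 months. Of the marked probe sets, 2609 were among those tested here, and each of these was called in the same direction when every probe set was tested on its own.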

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

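The tests of scaling, of separate handling of the ages, of the Y genes and of female RNA were chosen after the result was seen. The splits were chosen before. The second X chromosome, probe set, T lymphocyte and blood cell tests were chosen before their results, but after the patterns they address were seen. Of the T lymphocyte genes measured, Cd3e had been looked at before its test.

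In each age group of 5 arrays, a gene was singled out where the gap between its highest or lowest array and the nearest other array exceeded Dixon's 95% critical value of the group's range. Of 278 groups of 5, 18 were singled out, against about 13.9 that chance gives, and 7 of the 18 were in 30-month mouse 4. In that mouse Ifitm3 was highest at 2866 against 822 in the next mouse (ratio of gap to range 0.881), Cd74 at 808 against 428 (0.867) and Ly6c1 at 2720 against 1669 (0.799). Without that mouse the log2 change of Ly6c1 was 0.29 in place of 0.45. Hsph1 was highest in mouse 4 at 3956 against 3576 (0.766), H2-D1 at 1321 against 793 (0.759) and Cd52 at 351 against 238 (0.755), and Nr4a1 was lowest at 2209 against 2902 (0.733). In 30-month mouse 6 Rorb was lowest at 160 against 231 (0.853) and Cd68 highest at 337 against 277 (0.721). In 30-month mouse 2 Ctss was lowest at 2419 against 2627 (0.780), and in 30-month mouse 3 Glb1 was highest at 557 against 508 (0.768).

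At 5 months, Arc was highest in mouse 3 at 4359 against 3845 (0.864). In mouse 5 Per3 was lowest at 539 against 615 (0.849), Flt1 highest at 363 against 314 (0.773) and Slc2a1 lowest at 646 against 858 (0.719). In mouse 1 Cyp51 was highest at 396 against 352 (0.799) and Psma4 at 2812 against 2505 (0.769), and in mouse 4 Dcx was highest at 519 against 446 (0.717).

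The first pattern is the number of genes and lists called between the ages. Of 100 splits of the 10 arrays into 5 and 5, only 1, the real one, gave as many genes higher (4068), as many lower (1466) or as many lists (15). The other splits gave at most 363 genes in their larger direction, which was set against both counts, and at most 2 lists. This argues against a chance division of the arrays but does not exclude it, since 1 in 100 is the smallest share that 100 splits can give. The other splits also mix the ages, which adds the difference between the ages to the spread within their groups. The scaling of the arrays as the whole cause of the number called is argued against by 5178 genes called after quantile normalization; it could still have made the share of higher genes, which was 53% there, because that step centres the changes and so decides nothing. Separate handling of the arrays of each age may add to the pattern and cannot be told apart from age, since all 5 old arrays and no young array carry a mark in the column name. Age itself stays open as the explanation, untested against such handling.

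The second pattern is Xist, the transcript that silences 1 X chromosome in females, which was 2552 in 30-month mouse 6 and between 136 and 301 in the other 9 mice, all of them male by the labels. A female mouse, such as one under a wrong label, is excluded. The median log2 deviation of 4 Y genes from the other old mice was 0.0096 in this mouse, within the −0.18 to 0.09 of the others. An exchange with another male mouse would not show in the Y genes and was not tested. Female RNA mixed in remains open only as a share too small to show in the Y genes. The 5 X genes that escape inactivation had a median deviation of 0.49, against −0.14 to −0.01 in the others. A share of female RNA large enough for this would also lower the Y genes. Ddx3y was at 0.05, Uty at −0.03, Kdm5d at −0.08 and Eif2s3y at 0.23, none of them below the range of the others. On this 1 array these values argue against a share that large, although no female array was measured here to set that share. A second X chromosome beside the Y may also account for it, since the escape genes Ddx3x and Pbdc1, not looked at before, had a median deviation of 0.32 in this mouse and −0.17 to 0.08 in the others. This is a hypothesis. Female RNA would raise such genes too, but the Y genes argue against a share that large. Pbdc1 (0.49) and the genes seen before, Kdm6a (0.51) and Eif2s3x (0.55), stood above the other old mice (at most 0.03). Ddx3x was at 0.16 with up to 0.12 in the others, and Kdm5c at 0.08 with up to 0.19.

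The third pattern is the high level of interferon-inducible genes in 30-month mouse 4, where Tgtp1 was 1187 against 99 to 148 in the other 9 mice, Igtp 878, Iigp1 666 and Irgm1 585, all chosen after their values were seen. Defects of single probe sets are excluded, since the interferon-inducible genes Gbp7, Irf1 and Samhd1, not looked at before, had a median deviation of 0.51 in this mouse and −0.46 to 0.17 in the others. T lymphocytes in the tissue may contribute but the test does not decide: their 3 measured genes had a median deviation of 0.12 (others −0.19 to 0.06), above the range the prediction asked for, yet Cd3e was −0.11 and Lck 0.21, and the rule that members going both ways decide nothing was set after this was seen. Blood monocytes and granulocytes could not be tested, as 0 of their genes lay above the filter. A response of the tissue of this mouse itself was not tested, and the labels give no group that would separate it.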

How the results depend on the processing

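The authors' marks and leaving out 30-month mice 4 and 6 were alternatives chosen after seeing the data; the others were fixed before. For genes higher (4068), the count was 2602 with the same median per array, 435 at a fold of at least 1.5, 6561 with every probe set counted and 2667 by the authors' marks, the last 2 in probe sets. For genes lower (1466), it was 2433 after quantile normalization, 2702 with the same median per array, 848 above the 75th percentile, 2664 with every probe set, 839 at an adjusted p under 0.01, 237 at a fold of at least 1.5 and 688 by rank separation. Stricter thresholds and filters lower a count by construction. Setting each array to the same median moves every log2 change by the same amount. The median change over all tested genes went from 0.08 to −0.01 with that step, and to 0.0049 after quantile normalization. This moves genes from higher to lower by construction. Whether the general shift that these scalings remove came from the tissue or from the arrays was not tested. For the lists called (15), camera gave 6 at the preset and 0 at the estimated correlation (lowest adjusted p 0.571). Leaving out each array gave 3571 to 4147 genes higher, 1199 to 1547 lower, 14 to 16 lists and a difference in median signal of −0.03 to −0.01. Without 30-month mice 4 and 6 there were 3806 genes higher, 1139 lower and 14 lists. The other settings kept each count within 1.5 times. For the replicate block, deviations of same-numbered mice correlated across genes at −0.33, −0.04, 0.08 and 0.11, and none matched its own number best, so the numbers do not pair the mice. With the replicate block over 8 mice there were 3467 genes higher, 1007 lower and 10 lists, against 3786, 1192 and 12 for these mice without it. With the replicate block the striatum list gained a call (adjusted p 0.0225), and the interneuron (0.0521), clock (0.10), antioxidant (0.112), myelin (0.129), immediate-early (0.176) and calcium (0.220) lists did not pass. The interneuron list was counted as reversed under camera, although its own median stayed above 0 (0.081). Camera compares a list with the other genes, and both cameras placed it below them without a call (adjusted p 0.921 at the preset and 0.951 at the estimated correlation). With the probe sets of a gene averaged, Gria4 (−0.040, adjusted p 0.616), Psmc2 (−0.052, 0.433) and Sdhd (0.013, 0.892) reversed in sign, but were not called in the new direction. So did Psmc2 (−0.11, 0.0996) without x_at and s_at probe sets. The cause was not tested. Of the values of single named genes, 1302 kept their side and 48 lost their call when 1 array was left out. Under the other settings 2075 kept it, 171 lost it and 4 reversed. Of the 171 losses, 77 came at a fold of at least 1.5 and 13 at an adjusted p under 0.01, by construction. An adjusted p under 0.10 cannot lose a call. For lists, 307 kept it, 9 lost and 4 gained a call with 1 array left out. Under the others 246 kept it, 37 lost, 3 gained and 2 were counted as reversed, the interneuron list under each camera. Of the 37 losses, 14 came with camera at the estimated and 8 at the preset correlation, where the test asks another question than fry. The authors' pairwise calls were not run, since no such calls were in the files used here. Signal near the background limits what weak probe sets can show.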

Other observations

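The values below were chosen after the data were seen, and no test of an explanation was run on them. Along the first principal component of the tested genes, which held 56.9% of the variance, the 5 young arrays lay between −22.7 and −9.36 and the 5 old arrays between 9.69 and 21.5. Within the young arrays alone, the first axis of variation correlated with the age change across genes with an absolute r of 0.361, and within the old arrays with one of 0.305; genes are not independent replicates.

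The transthyretin gene Ttr, abundant in choroid plexus, had signals of 4666, 10851, 2898, 3460 and 10050 in the 5 old mice, and of 7969 to 10541 in the young mice. A probe set of Chd7 read 105818 in 30-month mouse 5 and at most 112 in each other array, which was the highest value of the table. For the 5 X genes that escape inactivation, the log2 change with age at the deposited scaling was 0.84 for Kdm5c (adjusted p = 5.36e-06), 0.52 for Kdm6a (adjusted p = 9.90e-04), 0.29 for Pbdc1 (adjusted p = 0.0327), 0.13 for Eif2s3x (adjusted p = 0.360) and −0.22 for Ddx3x (adjusted p = 0.00856), with 30-month mouse 6 included.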
